A study of Homo sapiens with 17 samples.

How the data were processed

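The series measured messenger RNA in 4 lymphoblastoid cell lines, which are B cells immortalised with Epstein-Barr virus and kept by a repository. Each line was divided into 17 cultures. Per the labels, 1 culture of each line was collected before treatment (0 h), and the others received water or a single bolus of hydrogen peroxide at 9, 90 or 900 µM and were collected 4, 12, 24 or 48 h later. RNA of the 4 lines was pooled in equal parts for each dose and time, and each pool was hybridised to 1 Affymetrix Human Gene 1.0 ST array, which gave 17 arrays. The treatment text speaks of water for the control cultures, while the sample characteristics call them untreated; they are called water here.

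The deposited table holds log2 expression values for 33297 probes, made by the authors with robust multi-array average (RMA, which corrects background, normalises quantiles between arrays and summarises probes), per the submitters' processing notes; the version of RMA, the genome build and the annotation they used are not given in the sources used here. Values ran from 1.62 to 14.4. They were used as deposited, with no filter and no further normalisation. Arrays give no read depth, and their number limits the precision.

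Probes were named through the platform annotation. In it 19460 probes carried 1 gene symbol, 1754 carried several and 12083 had none. Symbols were compared by gene identifier with RefSeq gene names of assembly GRCh38.p14, used for names only; 19429 of the single-gene probes had their identifier there and 0 symbols changed. Probes with several symbols or none were left out of the gene tests. Of the 18417 genes tested, 769 had several probes, and the probe of highest mean signal stood for the gene. Genes of X inactivation and of the Y chromosome are not reported.

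All tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, with the data.table package, version 1.17.8, for input). There was 1 array per dose and time and no replicate. One fit of all 17 arrays had 11 coefficients: the level before the bolus, the water level at each of the 4 times, 1 effect each of 9 and 90 µM over all times, and an effect of 900 µM at each time. The spread, on 6 residual degrees of freedom, came from departures of the water, 9 and 90 µM arrays from additive effects of dose and time, and the 900 µM and 0 h arrays, which leave no residuals, were assumed to vary like these. The p-values therefore rest on these departures and not on a spread between replicate pools. The departures mix technical noise with any real difference in the effect of a low dose between times. The water array at 4 h had the largest residual SD over genes, 0.2097, against 0.08281 to 0.146 for the other 11 arrays. The p-values say nothing of the spread between lines. The prior degrees of freedom were 6.1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The median half-width of the 95% interval was 0.4 log2 for a single-time effect of 900 µM, 0.23 for an effect averaged over time and 0.27 for a change between times after the bolus. Changes with culture time were differences between the fitted water levels, to which the 9 and 90 µM arrays contribute.

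Lists fixed by gene symbol, 29 in all, covered NRF2 targets, p53 targets, the heat shock response, the integrated stress response, endoplasmic reticulum (ER) chaperones, immediate early genes, NF-kB targets, antioxidant enzymes, metallothioneins, iron handling, DNA replication and G1/S, mitosis and G2/M, replication-dependent histones, base excision repair, homologous recombination and Fanconi genes, apoptosis regulators, cholesterol synthesis, interferon-stimulated genes, hypoxia and glycolysis, nucleolar ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, autophagy and lysosome, B cell identity, plasma cell differentiation, markers of T and NK cells, of myeloid cells and of fibroblasts, and genes that can differ between such lines. Small nucleolar RNAs, 192 genes, formed a further list, chosen as a marker of RNA composition and quality. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists within a comparison. Members past the threshold were counted both over all genes and adjusted over the list alone. Some genes belonged to several lists, so the shifts of different lists are not independent. The class of immunoglobulin variable genes had 1 gene with a probe and was not tested.

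Genes were named by a rule. For the effects of 900 µM at single times, the averages of each dose over time and the change from 4 to 48 h, it took the 10 largest rises and the 10 largest falls past the threshold; the averages also needed 1 sign at all 4 times. It added up to 2 members per list and direction past the threshold for 900 µM at 4 and 48 h. Where no gene passed, it took the 3 of smallest p in each direction. HMOX1, CDKN1A, GDF15 and CAT were always reported. Other list members are named as examples and were chosen after their values were seen.

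The model, the lists, the naming rule and the alternatives were chosen before the data were examined, except that all results were also computed without the water array at 4 h, an alternative added after that array was seen to stand apart. The other alternatives left out genes of low mean signal (under 5.55 log2), tested all probes, repeated quantile normalisation, centred each array on its cytosolic ribosomal protein genes, used a trended and robust prior variance, replaced a gene's probe of highest signal by the mean of its probes, used an additive model or no time block for the averages, and left out the 9 µM arrays, the 90 µM arrays or each time in turn.

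The fit was tested on simulated data with known changes in 50 genes of each size among the 18417 genes. The simulated noise was independent and normal, with the same SD in all arrays for a given gene. It thus built in that the 900 µM arrays vary like the others, and held no array that stands apart. False calls in the real data may therefore be more frequent than in the simulation. For 900 µM at 12 h it recovered 2 genes changed by 0.5 log2, 41 changed by 1, 48 changed by 1.5 and 50 changed by 2, with 5 false calls among 146. For the average of 900 µM over time it recovered 36 at 0.5 log2 and 50 at each larger size, with 7 false calls among 193. For the average of 90 µM it recovered 37 at 0.5 log2 and 50 at each larger size, with 10 false calls among 197. For the change from 4 to 48 h it recovered 22 at 0.5, 49 at 1 and 50 at each larger size, with 9 false calls among 180. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.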

Results

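Gene expression was measured in pooled RNA of 4 lymphoblastoid cell lines (B cells immortalised with Epstein-Barr virus) before and after a bolus of hydrogen peroxide, an oxidant that cells remove with catalase, peroxiredoxins and glutathione peroxidases. The 17 arrays comprised 1 before the bolus and 1 for each of water, 9, 90 and 900 µM at 4, 12, 24 and 48 h. The comparisons ask which genes each dose changed, when, and how the cultures changed with time apart from a constant effect of 9 and 90 µM. Values are log2 changes with the standard error (SE) of the limma fit, and p-values are adjusted over all genes tested unless stated.

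The water array at 4 h stood apart from the others. Its correlation with each of the other 16 arrays over all 33297 probes lay between 0.9713 and 0.9775, whereas r between any of those 16 lay between 0.9852 and 0.995. Its values had an SD over these probes of 2.211, against 2.348 to 2.419 elsewhere. The 9 µM array at 4 h differed from it by 2-fold or more in 488 genes, but from the array before the bolus in 5 genes. All comparisons that use this array are therefore also given without it where their count moved by over 1.5 times.

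**Figure D1:**
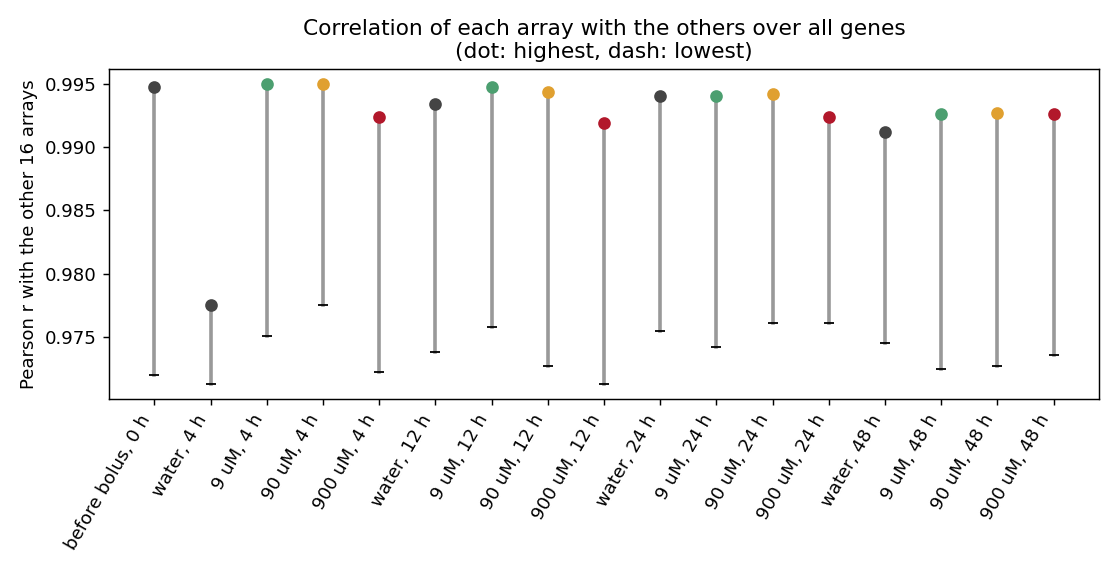
Highest (dot) and lowest (dash) Pearson correlation of each of the 17 arrays with the other 16 over all 33297 probes (called genes in the title), by dose and time. The highest value of the water array at 4 h, 0.9775, lies below the lowest value between any of the other 16, 0.9852.

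Averaged over the 4 times, 900 µM peroxide raised 20 of 26 p53 targets and 4 of 20 targets of the oxidant sensor NRF2, and lowered 3 of 19 histone genes. With an estimated correlation none of these lists passed (adjusted p = 0.057, 0.19 and 0.19), whereas all 3 did without the water array at 4 h (adjusted p = 0.039, 0.026 and 0.026), as did NF-kB targets (adjusted p = 0.039). TP53I3, a p53-induced quinone oxidoreductase, rose by 1.49 ± 0.14 (2.82-fold, adjusted p = 0.00053), and GDF15, a secreted stress factor and p53 target, by 1.65 ± 0.18 (3.13-fold, adjusted p = 0.0018). HMOX1, which encodes haem oxygenase 1, rose by 1.36 ± 0.16, and NQO1, an NRF2-induced quinone reductase, by 1.17 ± 0.11. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, rose by 1.22 ± 0.17. TXNIP, which encodes a thioredoxin-binding protein, fell by 1.11 ± 0.13 (adjusted p = 0.0032).

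Of 26 measured p53 targets, 20 rose, 0 fell and 6 did not pass (24 higher adjusted over the list alone, median 0.73, camera adjusted p = 4.9e-36, adjusted p = 0.057 with an estimated correlation). Among them GADD45A, which acts in growth arrest after DNA damage, rose by 1.11, the stress-induced sestrin SESN1 by 1.08, the phosphatase gene PPM1D by 1.02 and MDM2, whose product degrades p53, by 0.98. Of 20 NRF2 targets, 4 rose and 16 did not pass (10 higher adjusted over the list alone, camera adjusted p = 1.6e-09, adjusted p = 0.19 with an estimated correlation). Besides HMOX1 and NQO1 these were thioredoxin (TXN, 0.53) and sulfiredoxin (SRXN1, 0.61). Of 17 heat shock genes, DNAJB1 (0.70), HSPA6 (0.69) and DNAJA1 (0.53) rose and 14 did not pass (10 higher adjusted over the list alone, 4 without the water array at 4 h, camera adjusted p = 3.6e-10, adjusted p = 0.19 with an estimated correlation). Against the single water array the heat shock median after 9, 90 and 900 µM was 0.19, 0.21 and 0.25 at 12 h. At 24 h it was -0.11, 0.23 and 0.19, and at 48 h 0.06, 0.04 and 0.35. Of 25 apoptosis regulators, PMAIP1 (0.81), which encodes the BH3-only protein NOXA, and the death receptor genes TNFRSF10B (0.70), FAS (0.55) and TNFRSF10A (0.52) rose and 21 did not pass (7 higher adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.27 with an estimated correlation). TNFRSF10B and FAS were also on the p53 list. DNAJB1 (0.56, adjusted p = 0.064), HSPA6 (0.61, adjusted p = 0.065) and TNFRSF10A (0.47, adjusted p = 0.067) did not pass without the water array at 4 h. CAT, which encodes catalase, was at 0.01 ± 0.12, and at -0.13 without that array, and did not pass.

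Of 19 replication-dependent histone genes, H2BC3 (-0.86), H1-3 (-0.76) and H1-5 (-0.56) fell and 16 did not pass (12 lower adjusted over the list alone, median -0.41, camera adjusted p = 2.7e-11, adjusted p = 0.19 with an estimated correlation). Leaving out the water array at 4 h, 12 histone genes fell. Further histone genes among the largest falls, outside that list, were H2AC21 (-0.87), H3C12 (-0.77) and H4C2 (-0.75). Of 25 hypoxia and glycolysis genes, 5 fell, with PFKFB4, a regulator of glycolysis, at -0.84 and the glucose transporter gene SLC2A3 at -0.56 (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00013, adjusted p = 0.28 with an estimated correlation). A lower median of this list was not particular to 900 µM. All doses were set against the same water array at each time, so a high level in that array would lower each median. Against the single water array the list median after 9, 90 and 900 µM was -0.09, -0.12 and -0.14 at 12 h. It was -0.19, -0.08 and -0.24 at 24 h, and -0.10, -0.23 and -0.19 at 48 h. PFKFB4 was at -0.59 after 9 µM, which did not pass. Other large falls were those of ALDH1L2 (-0.93), a mitochondrial folate enzyme, of CD180 (-0.90), a surface receptor of B cells, and of EVI2A (-0.83). Other large rises were those of CMBL (1.32), of the kinase gene PLK2 (1.29), of the cytokine genes IFNG (1.71 ± 0.31) and TNFSF4 (1.26), and of the small nucleolar RNAs SNORD50B (1.22) and SNORD12C (1.17). IFNG and PLK2 had a mean signal under 5.55 log2, called low below.

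Camera at the preset correlation shifted 20 of 30 lists for this average, 14 upward and 6 downward, and fry, which asks whether a list moves on balance and does not compare it with other genes, called 7. Several lists shifted upward by camera with few members past the threshold. Immediate early genes (20 measured) included rises of JUN (0.59) and IER3 (0.72), with 8 higher adjusted over the list alone (camera adjusted p = 2.1e-06, adjusted p = 0.19 with an estimated correlation). NF-kB targets (19 measured) included a rise of CD83 (0.52), an activation marker of B cells, with 12 higher adjusted over the list alone (camera adjusted p = 2.9e-11, adjusted p = 0.27 with an estimated correlation). Metallothioneins (9 measured) had 0 members past the threshold and 5 higher adjusted over the list alone (median 0.36, camera adjusted p = 1.3e-05, adjusted p = 0.28 with an estimated correlation). Antioxidant enzymes (24 measured) included rises of SESN1 and TXN only, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.1e-05, adjusted p = 0.32 with an estimated correlation). SESN1 was also on the p53 list and TXN on the NRF2 list. Oxidative phosphorylation genes (25 measured) included a rise of COX7B (0.73, and 0.61 with adjusted p = 0.073 without the water array at 4 h), with 3 higher adjusted over the list alone (camera adjusted p = 9.6e-07, adjusted p = 0.32 with an estimated correlation). Nucleolar ribosome biogenesis (19 measured) had 0 members past the threshold and 5 higher adjusted over the list alone (camera adjusted p = 2e-06, adjusted p = 0.28 with an estimated correlation).

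The medians of 5 further lists that shifted upward were small, and centring on ribosomal protein genes, which moved the median of all genes by -0.16, turned their sign. Each is given as deposited, after centring and then relative to the moved median of all genes, above which all 5 stayed. Small nucleolar RNAs, which guide modification of ribosomal RNA, had 11 of 192 members higher and 26 adjusted over the list alone, with medians of 0.11, -0.04 and 0.13 (camera adjusted p = 5.5e-07, adjusted p = 0.28 with an estimated correlation). Cytosolic ribosomal proteins (25 measured) had 0 members past the threshold in either count, with a median of 0.15, which is near 0 after this centring by construction (-0.01, and 0.16 relative to all genes, camera adjusted p = 3.2e-05, adjusted p = 0.28 with an estimated correlation). Autophagy and lysosome genes (23 measured) had 0 past the threshold and 2 higher adjusted over the list alone, with medians of 0.14, -0.02 and 0.15 (camera adjusted p = 0.0017, and 0.22 without the water array at 4 h, adjusted p = 0.49 with an estimated correlation). Iron handling genes (13 measured) had HMOX1 past the threshold and 4 higher adjusted over the list alone, with medians of 0.09, -0.07 and 0.10 (camera adjusted p = 0.0017, adjusted p = 0.41 with an estimated correlation). Apoptosis regulators, with 4 members past the threshold, had medians of 0.04, -0.12 and 0.05.

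Mitosis and G2/M genes (24 measured) had 0 members past the threshold and 16 lower adjusted over the list alone (median -0.32, camera adjusted p = 2.7e-11, adjusted p = 0.27 with an estimated correlation). B cell identity genes (16 measured) included falls of the B cell signalling gene BANK1 (-0.55) and of CD72 (-0.54), with 4 lower adjusted over the list alone (camera adjusted p = 0.01, adjusted p = 0.49 with an estimated correlation). The integrated stress response list (22 measured) included a fall of the serine synthesis gene PHGDH (-0.72), with 2 higher and 2 lower adjusted over the list alone (median -0.15, camera adjusted p = 0.011, adjusted p = 0.61 with an estimated correlation). Homologous recombination and Fanconi genes (16 measured) had 0 past the threshold, with 1 higher and 3 lower adjusted over the list alone (median -0.15, camera adjusted p = 0.027, adjusted p = 0.49 with an estimated correlation).

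The other 10 lists did not shift at the preset correlation, and with an estimated correlation their adjusted p ran from 0.61 to 0.92. Within them XBP1 (-0.51), a transcription factor of the unfolded protein response and of plasma cells, and SEL1L (-0.44) fell among 16 ER chaperone genes (2 lower adjusted over the list alone, camera adjusted p = 0.39). XBP1 also belonged to the 13 plasma cell genes (2 lower adjusted over the list alone, camera adjusted p = 0.058). PCNA, the sliding clamp of DNA polymerase and a p53 target, rose by 0.69 among 27 DNA replication and G1/S genes (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.39). VCAN, of low signal, rose by 0.47 among 13 myeloid markers (1 higher adjusted over the list alone, camera adjusted p = 0.85). No member passed among 19 base excision repair genes (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.85), 16 cholesterol synthesis genes (0 adjusted over the list alone, camera adjusted p = 0.83) or 23 interferon-stimulated genes (0 adjusted over the list alone, camera adjusted p = 0.85). The same held for 16 T and NK cell markers (0 adjusted over the list alone, camera adjusted p = 0.31), 12 fibroblast markers (1 higher adjusted over the list alone, camera adjusted p = 0.62) and 11 genes that can differ between lines (2 lower adjusted over the list alone, camera adjusted p = 0.56).

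Leaving out the water array at 4 h, the members past the threshold were 3 lower in the integrated stress response, 4 lower in plasma cell genes, 2 higher in NF-kB targets and 1 lower each in mitosis, homologous recombination and base excision repair genes, autophagy genes and genes that can differ between lines.

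In all, 201 genes changed on average after 900 µM by limma, 139 higher and 62 lower, and 2659 had an unadjusted p under 0.05. There were 340 without the water array at 4 h, 171 higher and 169 lower, of which 186 were among the 201. ALDH1L2 then had an adjusted p of 0.064. Leaving out the arrays of 1 time gave 464 genes without 4 h, 190 higher and 274 lower, so that the balance turned. It gave 7 without 12 h (6 higher), 69 without 24 h (60 higher) and 89 without 48 h (69 higher). Centring on ribosomal protein genes gave 68 higher and 235 lower genes. Relative to the moved median the p53 list was at 0.75, the NRF2 list at 0.31, mitosis genes at -0.31 and histones at -0.40.

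**Figure D2:**
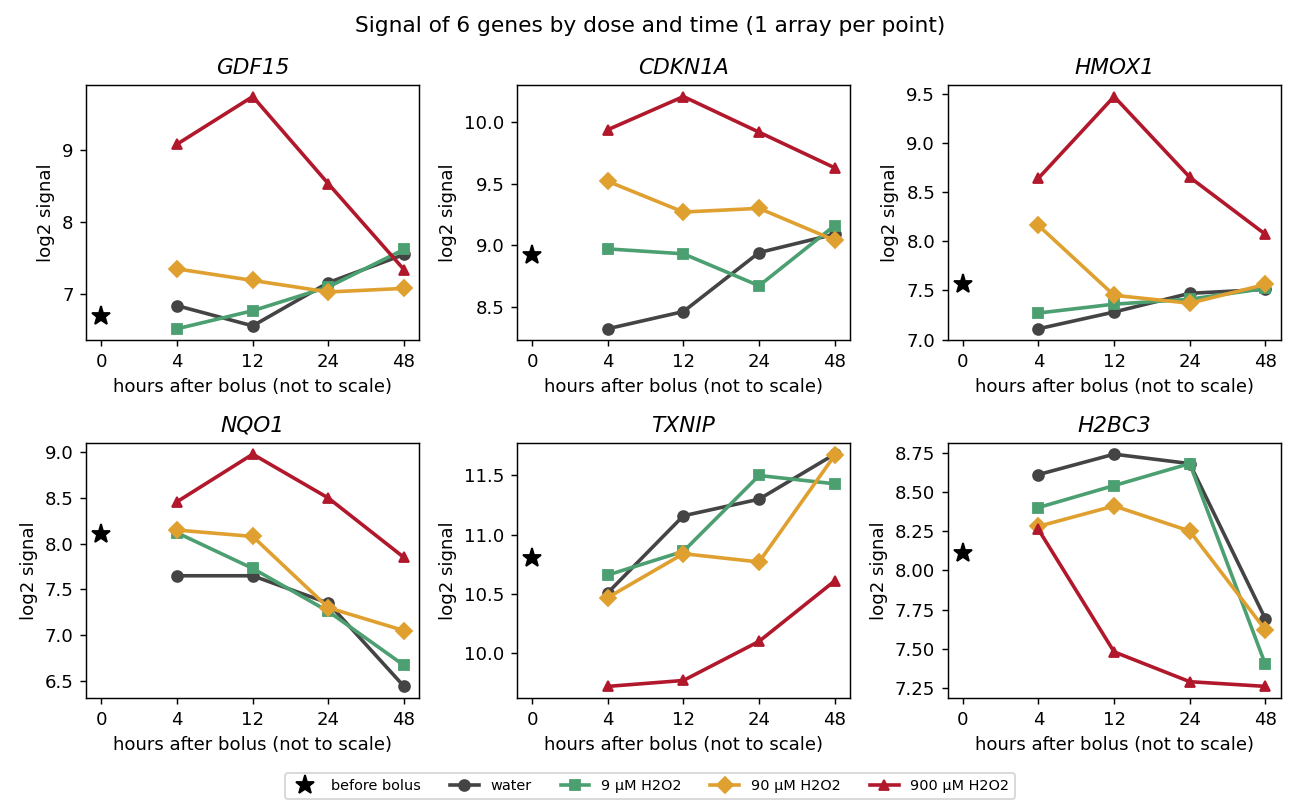
Log2 signal of 6 genes (vertical axes) against hours after the bolus (horizontal axes, not to scale), 1 array per point, with water and each dose as a line and the array before the bolus as a star. In the limma fit, which smooths the water levels with the 9 and 90 µM arrays, GDF15 after 900 µM was 2.94 above water at 12 h and -0.03 from it at 48 h, while NQO1 was 1.34 above water at 12 h and 1.31 at 48 h.

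At 4 h after 900 µM, 3 of 26 p53 targets rose, and the list did not pass with an estimated correlation (adjusted p = 0.25). GDF15 was 2.21 ± 0.32 above water (4.62-fold, adjusted p = 0.027), GADD45A 1.29 ± 0.17 and PPM1D 2.83-fold (adjusted p = 0.041). PMAIP1 rose by 1.28 ± 0.14 (adjusted p = 0.0095), and JUN, an immediate early transcription factor gene, by 1.10 ± 0.17. CDKN1A at 1.28 ± 0.30 (adjusted p = 0.13), HMOX1 at 1.24 ± 0.27 (adjusted p = 0.12) and CAT at 0.38 ± 0.20 (adjusted p = 0.35) did not pass. CAT was at 0.09 without the water array at 4 h.

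Camera at the preset correlation shifted 19 of 30 lists at 4 h, 17 upward and 2 downward, and fry called 6. Of the 26 p53 targets, 3 rose at 4 h and 23 did not pass (17 higher adjusted over the list alone, median 0.78, camera adjusted p = 8.2e-15, adjusted p = 0.25 with an estimated correlation). Of 17 heat shock genes 0 passed (6 higher adjusted over the list alone, median 0.53, camera adjusted p = 1.3e-07, adjusted p = 0.25 with an estimated correlation). Of 20 NRF2 targets 0 passed (9 higher adjusted over the list alone, median 0.43, camera adjusted p = 1.1e-06, adjusted p = 0.31 with an estimated correlation). Of 19 NF-kB targets 0 passed (7 higher adjusted over the list alone, median 0.48, camera adjusted p = 1.7e-07, adjusted p = 0.33 with an estimated correlation). Among small nucleolar RNAs SNORD50B (1.55), SNORD54 (1.24) and SNORA29 (1.09) rose (12 higher adjusted over the list alone, median 0.22, and -0.10 with ribosomal centring or 0.24 relative to all genes, camera adjusted p = 8.4e-06, adjusted p = 0.34 with an estimated correlation). Myeloid markers had a median of -0.36 (camera adjusted p = 0.0097, adjusted p = 0.25 with an estimated correlation) and T and NK cell markers one of -0.20 (camera adjusted p = 0.032, adjusted p = 0.34 with an estimated correlation). These medians depended on the water array at 4 h. Without it the medians were 0.60 for p53 targets, 0.46 for heat shock, 0.28 for NRF2 targets, 0.14 for NF-kB targets, 0.32 for small nucleolar RNAs, -0.12 for myeloid and -0.10 for T and NK cell markers, and the T and NK list no longer shifted (camera adjusted p = 0.20). Adjusted over the list alone, 4 NRF2 targets were then higher. Of p53 targets and of small nucleolar RNAs 1 each then rose, and the median of histones went from -0.06 to -0.41.

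The other large rises at 4 h were PLK2 (1.73), ANKRA2 (1.54), C2orf76 (1.51), OR52N4 (1.44), CFAP43 (1.39), FAP (1.36) and TXK (1.34), and the falls were OTUD6A (-1.23), BPIFA3 (-0.95) and ZNF366 (-0.95). All of these but ANKRA2 had low signal. Limma called 25 genes, 22 higher and 3 lower, of which 12 had low signal, and 3110 genes had an unadjusted p under 0.05. Only 12 genes were called without the water array at 4 h, 9 of them among the 25. Of the 18 genes named here as changed at 4 h, 10 did not pass then, which were GDF15 (2.18, adjusted p = 0.088), JUN (1.03, adjusted p = 0.084), PPM1D (1.18, adjusted p = 0.081), ANKRA2 (adjusted p = 0.091), C2orf76 (adjusted p = 0.062), SNORD50B (adjusted p = 0.11), SNORD54 (adjusted p = 0.081), SNORA29 (adjusted p = 0.051), OTUD6A (adjusted p = 0.094) and ZNF366 (adjusted p = 0.10). The count was 1 without the 90 µM arrays, 2 without the 9 µM arrays, and 0 with ribosomal centring, which moved the median of all genes by -0.32.

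At 12 h after 900 µM, 9 of 26 p53 targets and 3 of 20 NRF2 targets rose and 10 of 24 mitosis genes fell. With an estimated correlation none of these lists passed (adjusted p = 0.056, 0.18 and 0.12). When the water array at 4 h was left out, 3 lists passed, NRF2 targets (adjusted p = 0.036), histones (adjusted p = 0.036) and homologous recombination (adjusted p = 0.038). GDF15 rose by 2.94 ± 0.32 (7.66-fold, adjusted p = 0.0038), HMOX1 by 2.22 ± 0.27 (4.65-fold, adjusted p = 0.005), TP53I3 by 1.93 ± 0.23 and GADD45A by 1.83 ± 0.17. CDKN1A rose by 1.59 ± 0.30 (adjusted p = 0.036). KIF14, a kinesin of cytokinesis, fell by 1.47 ± 0.17 (adjusted p = 0.0042), HMMR, a mitotic spindle factor, by 1.39 ± 0.22, and KIF20A, another mitotic kinesin, by 1.38 ± 0.24. CAT was at -0.28 ± 0.20 (adjusted p = 0.74).

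Of the 26 p53 targets, 9 rose at 12 h and 17 did not pass (25 higher adjusted over the list alone, median 1.02, camera adjusted p = 3e-36, adjusted p = 0.056 with an estimated correlation). They included SESN1 (1.65), MDM2 (1.40), PPM1D (1.35) and the ribonucleotide reductase gene RRM2B (1.20). Of 24 mitosis and G2/M genes, 10 fell and 14 did not pass (22 lower adjusted over the list alone, median -0.80, camera adjusted p = 2.9e-32, adjusted p = 0.12 with an estimated correlation). Among them were the checkpoint kinase gene BUB1 (-1.22), the kinetochore gene CENPF (-1.22), the mitotic kinase gene PLK1 (-1.19) and TOP2A (-0.81), which encodes a topoisomerase. Of 19 histone genes, H2BC3 (-1.25) and H1-5 (-0.89) fell (10 lower adjusted over the list alone, median -0.64, camera adjusted p = 1e-14, adjusted p = 0.18 with an estimated correlation). Of 20 NRF2 targets, HMOX1, NQO1 (1.34) and SRXN1 (0.98) rose (10 higher adjusted over the list alone, camera adjusted p = 4.9e-10, adjusted p = 0.18 with an estimated correlation).

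At 12 h camera at the preset correlation shifted 24 of 30 lists, 13 upward and 11 downward, and fry called 5. The downward ones included 4 more lists with few members past the threshold. Of 16 homologous recombination and Fanconi genes 0 passed (4 lower adjusted over the list alone, median -0.43, camera adjusted p = 1.9e-07, adjusted p = 0.20 with an estimated correlation). Of 16 cholesterol synthesis genes, FDPS (-0.90), which makes farnesyl diphosphate, fell (1 lower adjusted over the list alone, median -0.41, camera adjusted p = 2.3e-05, adjusted p = 0.35 with an estimated correlation). Of 25 hypoxia and glycolysis genes, PFKFB4 (-1.16) and the histone demethylase gene KDM3A (-0.72) fell (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 3e-05, adjusted p = 0.24 with an estimated correlation). BANK1 (-1.27) fell among 16 B cell identity genes (3 lower adjusted over the list alone, camera adjusted p = 1.6e-05, adjusted p = 0.29 with an estimated correlation).

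The remaining named rises at 12 h were SNORD115-44 (1.99), CMBL (1.85), the GTPase gene RRAD (1.76) and CEACAM1 (1.59), and the remaining named falls were CCDC18 (-1.39), ARHGAP11A (-1.33), NT5E (-1.29), TXNIP (-1.27) and ARHGEF6 (-1.23). SNORD115-44 and CEACAM1 had low signal. Limma called 128 genes, 67 higher and 61 lower (1899 at unadjusted p under 0.05), and ribosomal centring, which moved the median of all genes by -0.16, gave 39 higher and 118 lower. Without the water array at 4 h there were 525 genes, 212 higher and 313 lower, which included all 128, while 4 were called without the 90 µM arrays and 4 without the 9 µM arrays. All of these were higher, so that none of the 61 falls, the 10 mitosis genes among them, was called when either low dose was left out. With the water array at 4 h left out, 17 p53 targets and 6 NRF2 targets rose, and 17 mitosis, 12 histone, 7 hypoxia, 3 homologous recombination, 3 B cell and 2 cholesterol synthesis genes fell.

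At 24 h after 900 µM, 7 genes passed. TP53I3 rose by 2.24 ± 0.23 (4.74-fold, adjusted p = 0.0099), CMBL 3.02-fold, NQO1 by 1.37 ± 0.20, LACC1 by 1.11 ± 0.16 and RRAD by 1.03 ± 0.14, while the histone genes H2BC3 and H3C12 fell by 1.40 ± 0.18 and 1.23 ± 0.17. GDF15 at 1.47 ± 0.32 (adjusted p = 0.19), HMOX1 at 1.34 ± 0.27 (adjusted p = 0.17), CDKN1A at 1.22 ± 0.30 (adjusted p = 0.26) and CAT at -0.12 ± 0.20 (-0.22 without the water array at 4 h) did not pass. LACC1 had low signal.

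Of 30 lists, camera at the preset correlation shifted 16 at 24 h, 8 in each direction, and fry called 1, the p53 targets. Of these 26 genes 1 rose at 24 h and 25 did not pass (20 higher adjusted over the list alone, median 0.83, camera adjusted p = 5.4e-32, adjusted p = 0.076 with an estimated correlation). Of 19 histone genes 1 fell (13 lower adjusted over the list alone, median -0.69, camera adjusted p = 1.4e-19, adjusted p = 0.15 with an estimated correlation). Of 24 mitosis genes 0 passed (10 lower adjusted over the list alone, median -0.47, camera adjusted p = 1.7e-16, adjusted p = 0.30 with an estimated correlation). The integrated stress response list, the ATF4 programme of amino acid supply, had 0 of 22 members past the threshold and 10 lower adjusted over the list alone (median -0.56, camera adjusted p = 7.1e-14, adjusted p = 0.30 with an estimated correlation). At unadjusted p under 0.05 limma gave 1078 genes. Limma called 61 genes without the water array at 4 h, 25 higher and 36 lower, including all 7, and histones then passed with an estimated correlation (adjusted p = 0.043). In that fit 3 p53 targets rose, and 8 histone genes, 1 mitosis gene and 1 integrated stress response gene fell. Limma called 0 without the 90 µM arrays or without the 9 µM arrays, and 1 with ribosomal centring.

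At 48 h after 900 µM, no gene passed by limma (1062 at unadjusted p under 0.05), and 1 gene, VCAN, passed without the water array at 4 h (adjusted p = 0.032). The genes of smallest p were NQO1 (1.31 ± 0.20, adjusted p = 0.22), VCAN (1.14 ± 0.17, adjusted p = 0.22) and PSTPIP2 (0.95 ± 0.16), and ALDH2 (-0.87 ± 0.19, adjusted p = 0.46), RAPGEF2 (-0.75 ± 0.15) and TLX3 (-0.73 ± 0.15), none of which passed. VCAN had low signal. CDKN1A was at 0.80 ± 0.30, HMOX1 at 0.65 ± 0.27, CAT at 0.08 ± 0.20 (-0.02 without the water array at 4 h) and GDF15 at -0.03 ± 0.32. Of 30 lists, camera at the preset correlation shifted 15 at 48 h, 11 upward and 4 downward, and fry called 0. The integrated stress response list had 10 of 22 members lower adjusted over the list alone and 0 over all genes (median -0.59, camera adjusted p = 1.8e-15, adjusted p = 0.51 with an estimated correlation). The p53 targets had 6 of 26 higher adjusted over the list alone and 0 over all genes (median 0.44, camera adjusted p = 5.6e-13, adjusted p = 0.51 with an estimated correlation). DNA replication and G1/S genes (median 0.26, camera adjusted p = 3.6e-07, adjusted p = 0.51 with an estimated correlation) and cholesterol synthesis genes (median 0.31, camera adjusted p = 4.7e-06, adjusted p = 0.51 with an estimated correlation) had 0 members past the threshold in either count.

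**Figure D3:**
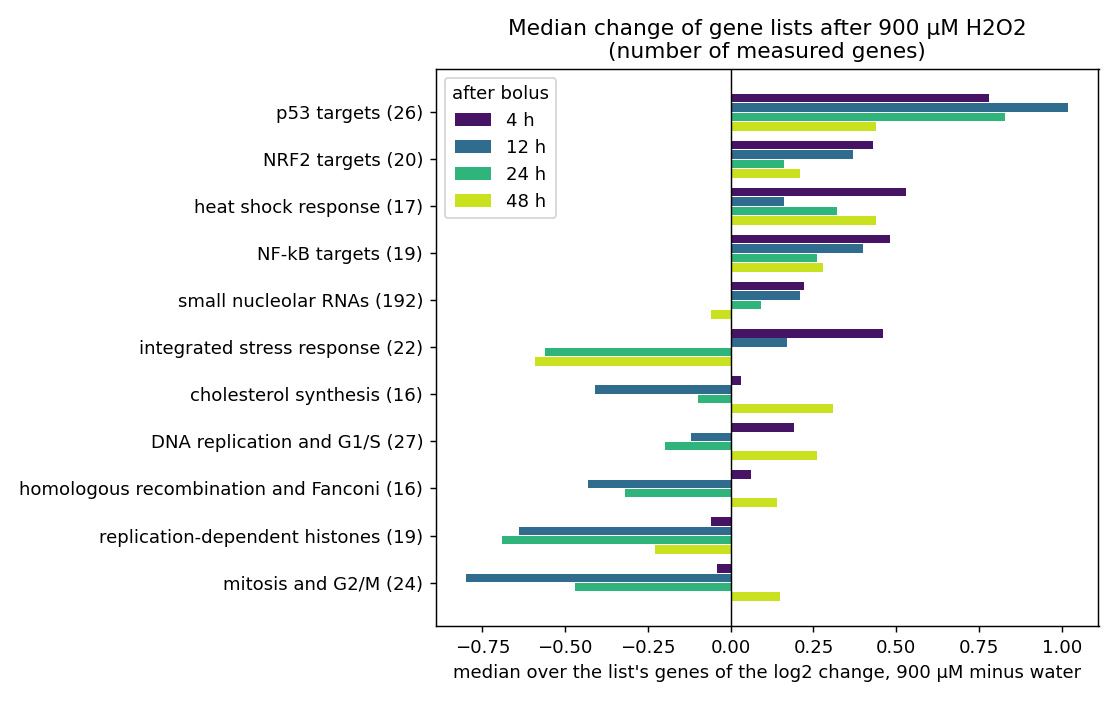
Median log2 change of 11 gene lists (bars, with the number of measured genes) after 900 µM relative to water, by hours after the bolus. The p53 list had medians of 0.78, 1.02, 0.83 and 0.44 at 4, 12, 24 and 48 h; with ribosomal centring, which moved all genes by -0.32 at 4 h, the medians at that time of small nucleolar RNAs, DNA replication, homologous recombination and cholesterol synthesis changed sign.

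The effect of 900 µM was not shown to differ between times for single genes by limma's F test (0 genes, smallest adjusted p = 0.18, 1410 at unadjusted p under 0.05 and 2436 without the water array at 4 h). Of the pairwise differences of the effect, 48 minus 12 h called 1 gene, the GTPase gene RRAD, and 25 genes without the water array at 4 h. The other 5 pairs called 0 genes (499 to 2025 at unadjusted p under 0.05), but 48 minus 4 h called 3 without that array. Between 12 and 48 h the effect on mitosis genes differed by a median of 1.02 (camera adjusted p = 4e-34, adjusted p = 0.21 with an estimated correlation and 0.042 with fry) and that on p53 targets by -0.55 (camera adjusted p = 2e-12, adjusted p = 0.23 with an estimated correlation).

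At 9 and 90 µM, no gene passed on average over the 4 times. After 90 µM the genes of smallest p were CMBL (0.69 ± 0.14), RPS27L, a p53-induced ribosomal protein homologue (0.66 ± 0.12), and SNORD14E (0.63 ± 0.13), and OR51A4 (-0.61 ± 0.11), LOC642696 (-0.56 ± 0.10) and HSPB7 (-0.37 ± 0.08), each with an adjusted p of 0.63. CDKN1A was at 0.58 ± 0.17, HMOX1 at 0.29 ± 0.16, CAT at 0.17 ± 0.12 and GDF15 at 0.13 ± 0.18 after 90 µM, with HMOX1 at 0.15 and CAT at 0.03 without the water array at 4 h. After 9 µM the genes of smallest p were SNORD50B (0.78 ± 0.14), ZNF737 (0.55 ± 0.10) and SNORA29 (0.44 ± 0.10), and OR51A4 (-0.88 ± 0.11, adjusted p = 0.10), PFKFB4 (-0.59 ± 0.12) and CYP4Z2P (-0.42 ± 0.09). CAT was at 0.23 ± 0.12, CDKN1A at 0.23 ± 0.17, HMOX1 at 0.05 ± 0.16 and GDF15 at -0.02 ± 0.18 after 9 µM. Without that array CAT was at 0.09, CDKN1A at 0.06, HMOX1 at -0.10 and GDF15 at -0.04. OR51A4, LOC642696, HSPB7 and CYP4Z2P had low signal.

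Camera at the preset correlation shifted 15 of 30 lists after 90 µM, 14 of them upward, and 16 after 9 µM, 14 of them upward, against 10 and 8 without the water array at 4 h, and fry called 0 for either dose. An upward shift after a low dose was therefore not particular to a list. Of the 26 p53 targets 0 passed after 90 µM over all genes and 16 were higher adjusted over the list alone, 10 without that array (median 0.31, camera adjusted p = 4.4e-15, adjusted p = 0.44 with an estimated correlation). Set directly against 9 µM, p53 targets had a median of 0.23 at 90 µM (0 members past the threshold in either count, camera adjusted p = 7.4e-20, adjusted p = 0.24 with an estimated correlation). The integrated stress response list had a median of -0.19 in the same comparison (0 members in either count, camera adjusted p = 9.6e-12, adjusted p = 0.99 with an estimated correlation). Histones had a median of -0.11 (0 members in either count, camera adjusted p = 0.00012, adjusted p = 0.99 with an estimated correlation). After 9 µM the p53 list had a median of 0.09, which went to -0.03 with ribosomal centring as all genes moved by -0.12, and was 0.08 relative to all genes (0 members in either count, camera adjusted p = 0.013, and 0.064 without the water array at 4 h, adjusted p = 0.59 with an estimated correlation).

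By limma, unadjusted p under 0.05 was reached by 1032 genes after 9 µM, 1295 after 90 µM and 213 between 90 and 9 µM. Without the water array at 4 h these were 680, 906 and 541, and again 0 passed. If no gene changed, a share of 0.05 of the 18417 genes is expected at this p. The 1032 genes after 9 µM were near that share, as were 1078 and 1062 for 900 µM at 24 and 48 h. Without the water array at 4 h the counts for 900 µM at 24 and 48 h were 2103 and 1733, above that share. The 213 genes between 90 and 9 µM were far below it, so p-values of this fit need not be well calibrated. The genes called for the average of 900 µM were then followed in the difference between 90 and 9 µM, which shares no array with the difference between 900 µM and water. Of the 139 genes higher after 900 µM, 119 (85.6%) were higher at 90 than at 9 µM, with a median of 0.14, and of the 62 lower genes 54 were lower, with a median of -0.09. Among all other genes 49.5% were higher at 90 µM.

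The change with culture time came from the water, 9 and 90 µM arrays together, with a constant effect of each dose taken out. In it 22 of 27 DNA replication genes and 20 of 24 mitosis genes fell between 4 and 48 h, and 17 of 23 interferon-stimulated and 19 of 22 integrated stress response genes rose. Camera at the preset correlation shifted 20 of 30 lists, 11 upward and 9 downward, and fry called 13. With an estimated correlation the interferon list passed (adjusted p = 0.02) and the others did not (adjusted p = 0.11, 0.11 and 0.13). The microRNA gene MIR146A, a target of NF-kB, rose by 2.60 ± 0.16 (6.05-fold, adjusted p = 2.2e-05), ASS1, which makes argininosuccinate, by 2.19 ± 0.22, the cystathionine lyase gene CTH by 1.78 ± 0.26 and CHAC1, a glutathione-degrading enzyme induced by ATF4, by 1.71 ± 0.22. CDC6, a licensing factor of replication origins, fell by 1.53 ± 0.12 (adjusted p = 0.00012), ESCO2, which acetylates cohesin, by 1.54 ± 0.12, and CCNE2, a G1/S cyclin, by 1.44 ± 0.17. NQO1 fell by 1.25 ± 0.13 (adjusted p = 4e-04).

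Of 27 DNA replication and G1/S genes, 22 fell, 0 rose and 5 did not pass (26 lower adjusted over the list alone, median -0.70, camera adjusted p = 2.6e-26, adjusted p = 0.11 with an estimated correlation). MCM10 (-1.29) and the flap endonuclease gene FEN1 (-1.11) were among them. Of 24 mitosis genes, 20 fell and 4 did not pass (23 lower adjusted over the list alone, median -0.74, camera adjusted p = 7.4e-23, adjusted p = 0.11 with an estimated correlation). They included KIF11 (-1.09) and TTK (-1.08). Of 16 homologous recombination and Fanconi genes, 9 fell (12 lower adjusted over the list alone, median -0.61, camera adjusted p = 8.5e-13, adjusted p = 0.11 with an estimated correlation). The nuclease genes DNA2 (-1.16) and EXO1 (-1.07) were among them. Of 19 histone genes, 8 fell, and 14 without the water array at 4 h (12 lower adjusted over the list alone, median -0.48, camera adjusted p = 4.5e-08, adjusted p = 0.20 with an estimated correlation). The other named falls were RNU5D-1 (-2.61 ± 0.49), ERCC6L (-1.52), FAM111B (-1.42), CLSPN (-1.36) and TRIP13 (-1.22).

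Of 23 interferon-stimulated genes, 17 rose, 0 fell and 6 did not pass (21 higher adjusted over the list alone, median 0.58, camera adjusted p = 3.3e-20), and this list was the 1 of 30 that passed with an estimated correlation (adjusted p = 0.02). Leaving out the water array at 4 h, 5 passed, which were interferon (adjusted p = 0.027), DNA replication (adjusted p = 0.012), homologous recombination (adjusted p = 0.012), histones (adjusted p = 0.032) and NF-kB (adjusted p = 0.032). Interferon-stimulated genes included IFIT2 (1.20), RSAD2 (0.95) and XAF1 (0.79). Of 22 integrated stress response genes, 19 rose and 3 did not pass (21 higher adjusted over the list alone, median 0.79, camera adjusted p = 4.3e-20, adjusted p = 0.13 with an estimated correlation). STC2 (1.53), DDIT3 (1.31) and TRIB3 (1.31) were among them. Of 19 NF-kB targets, 11 rose (14 higher adjusted over the list alone, median 0.54, camera adjusted p = 1.7e-11, adjusted p = 0.20 with an estimated correlation). The chemokine gene CCL4 (1.30) and the adhesion gene ICAM1 (0.84) were among them. The other named rises were TM6SF1 (1.95), HCAR3 (1.74), INHBE (1.63), TMEM140 (3.03-fold) and ALDH1L2 (1.45). GDF15 (0.51 ± 0.21, adjusted p = 0.18), CAT (0.26 ± 0.14), CDKN1A (0.16 ± 0.20) and HMOX1 (0.02 ± 0.18) did not pass. Without the water array at 4 h CAT was at 0.07, CDKN1A at -0.07 and HMOX1 at -0.17.

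In all, 1318 genes changed from 4 to 48 h by limma, 779 higher and 539 lower (3972 at unadjusted p under 0.05). There were 1694 without the water array at 4 h, 699 higher and 995 lower, of which 1070 were among the 1318. Centring on ribosomal protein genes moved the median of all genes by -0.14 and gave 398 higher and 986 lower genes. Limma called 194 genes without the 90 µM arrays and 153 without the 9 µM arrays.

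**Figure D4:**
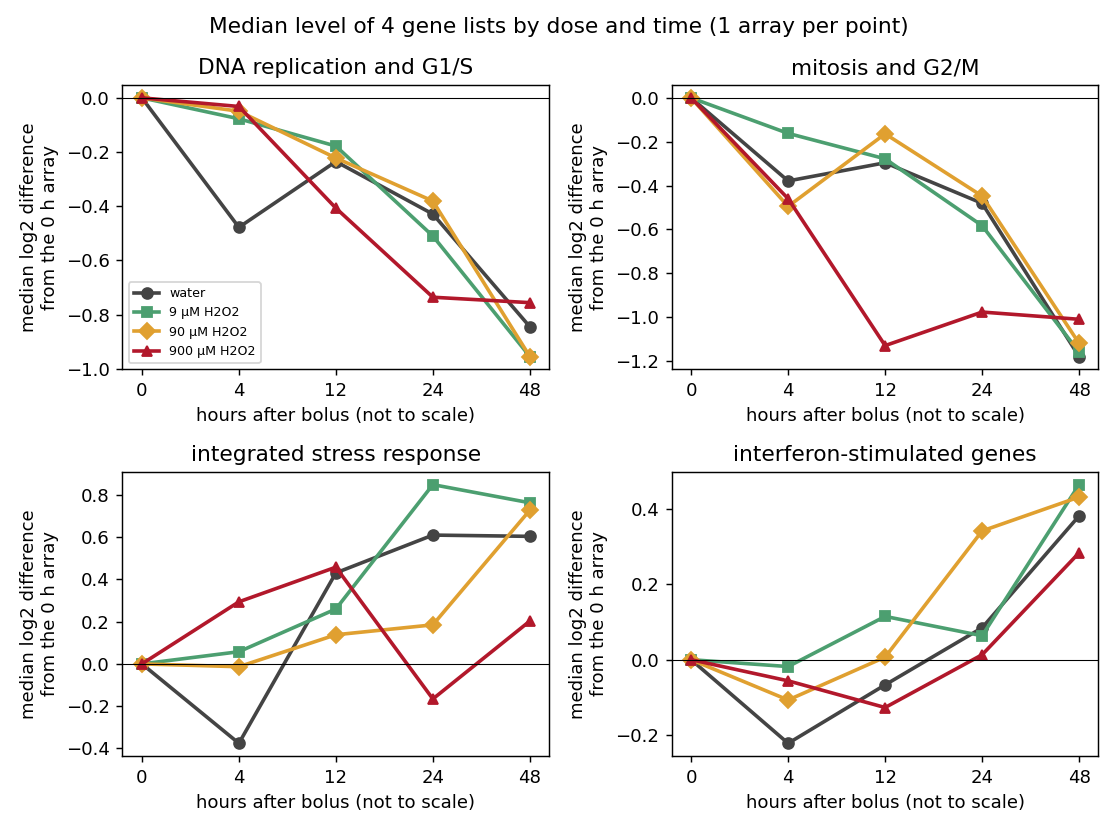
Median log2 level of 4 gene lists relative to the array before the bolus (vertical axes) against hours after the bolus (horizontal axes, not to scale), 1 array per point, for water and each dose. From 4 to 48 h the fit to the water, 9 and 90 µM arrays together gave medians of -0.70 for DNA replication and G1/S, -0.74 for mitosis, 0.79 for the integrated stress response and 0.58 for interferon-stimulated genes, and so departs from the water line alone, which went from -0.478 to -0.845 for DNA replication.

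Over shorter intervals no gene passed by limma. From 4 to 24 h 2066 genes had an unadjusted p under 0.05, from 4 to 12 h 2375, and from 0 to 4 h 2862. Without the water array at 4 h these were 1766, 1146 and 1236, and again 0 passed. Over these intervals camera at the preset correlation shifted 16, 13 and 18 of 30 lists, and fry called 1, 0 and 0. From 4 to 24 h the interferon-stimulated list had 15 of 23 members higher adjusted over the list alone, 6 without the water array at 4 h (median 0.35, camera adjusted p = 3.7e-13, adjusted p = 0.061 with an estimated correlation) and the integrated stress response list 21 of 22 higher and 1 lower (median 0.61, camera adjusted p = 5e-22, adjusted p = 0.29 with an estimated correlation). The lists of interferon (adjusted p = 0.045), DNA replication (adjusted p = 0.038) and homologous recombination (adjusted p = 0.038) passed with an estimated correlation without the water array at 4 h. From 4 to 12 h the integrated stress response list had 8 of 22 higher adjusted over the list alone, 0 without that array (median 0.40, and 0.22 without that array, camera adjusted p = 4.3e-08, adjusted p = 0.55 with an estimated correlation). From 0 to 4 h mitosis genes had 0 members past the threshold in either count (median -0.40, camera adjusted p = 1.8e-06, adjusted p = 0.54 with an estimated correlation).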

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

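The test of less change with culture time after 900 µM, the handling of the splits for the average of 900 µM and all values without the water array at 4 h were chosen only after the results were seen. The following differences between times passed a test of that pair of times. RRAD had an effect of 900 µM of 1.76 at 12 h and 0.14 at 48 h, a difference of -1.62 (SE 0.19, adjusted p = 0.032 within this pair, 1 of 6 pairs), while the F test over all times called 0 genes by limma (smallest adjusted p = 0.18, 1410 at unadjusted p under 0.05). For 7 lists the median effect had opposite signs at 12 and 48 h and camera at the preset correlation passed for the difference, while with an estimated correlation none passed (adjusted p from 0.21 to 0.36). Median differences, 48 minus 12 h, were 1.02 for mitosis and G2/M (-0.80 to 0.15, adjusted p = 4e-34), 0.43 for homologous recombination and Fanconi (-0.43 to 0.14, adjusted p = 2.2e-09) and 0.49 for DNA replication and G1/S (-0.12 to 0.26, adjusted p = 2e-08). They were 0.66 for cholesterol synthesis (-0.41 to 0.31, adjusted p = 2.2e-11), 0.21 for base excision repair (-0.13 to 0.09, adjusted p = 5e-04), -0.68 for the integrated stress response (0.17 to -0.59, adjusted p = 1.9e-13) and -0.26 for small nucleolar RNAs (0.21 to -0.06, adjusted p = 2.2e-08). Only mitosis, DNA replication and cholesterol synthesis shifted by camera at the preset correlation at both times, so the opposite signs of the other 4 lists are not settled. Those of mitosis, DNA replication and cholesterol synthesis are not settled either, since none of the 7 lists passed for the difference with an estimated correlation. Small nucleolar RNAs were above the single water array at both times (0.21 and 0.08, 114 of 192 above 0 at 48 h), and their negative sign arose only in the fitted water level, to which the 9 and 90 µM arrays, each 0.20 above water at 48 h, contribute. The integrated stress response was at 0.03 against the single water array at 12 h, and at 0.01 in the fit with ribosomal centring. That centring also took base excision repair at 48 h to 0.00. It moved the median of all genes by -0.16 at 12 h and -0.09 at 48 h, so the centred values do not place these lists relative to other genes.

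Probes without a gene name were outside the gene tests. With all probes tested, 78 of 12083 such probes passed for the average of 900 µM, 74 of them higher and 32 of low signal, against 0 for 9 µM. Of 1754 probes with several symbols 46 passed, all higher, and of 19460 with 1 symbol 144 passed, 113 of them higher.

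The water array at 4 h stood apart from the other 16. A compressed scale of that array is argued against as the whole cause, since its SD over genes from the other 4 h arrays went only from 0.426 to 0.374 after a trend on signal level was removed, against at most 0.23 for the other 11 arrays, although its slope of 0.885 (others 0.968 to 1.01) shows some compression. A response shared by cultures handled at 4 h is argued against by a slope of 0.073 over 460 genes between its shift from the water arrays at 12 and 24 h and the shift of the 9 and 90 µM arrays at 4 h from 0 h. A failure of this pool or array and a wrong label stay open, and no other biological explanation was tested.

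At 48 h the effect of 900 µM ran against the change with culture time. The water arrays that both comparisons share are argued against as the cause, since r over genes was -0.21 with the culture change taken as the mean of the 9 and 90 µM arrays alone (0.059 at 12 h, -0.043 at 24 h). For 9 and 90 µM at 48 h r was 0.17 and -0.033. Each of these used the culture change of the other low dose only, so the measures are not quite alike. Genes are not independent replicates. That cultures went through less of the change with time after 900 µM stays open, since the test of it used the arrays that show the pattern and restates it. Of 48 genes that rose 2-fold 89.6% were lower after 900 µM (median -0.54 against a rise of 1.18), and of 54 that fell 85.2% were higher (median 0.26 against -1.12). These values rest on 1 array at 900 µM, and cell number and medium were not measured in these data.

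All splits of the arrays of 2 groups into equal groups were counted, the real one included. For 900 µM 3 of 35 splits, the real one and 2 others, called as many genes, with the larger count of both labellings taken for each split (real 618, highest other 1245), so chance is not excluded. The 2 others, with 1245 and 1083 genes, swapped arrays within times. All 3 counts, the 618 of the real split included, came from the labelling with the water array at 4 h in the treated group, whose arrays leave no residuals. With it kept as a control, the real split called 201 genes and the highest other 15. For 9 µM, for 90 µM and for 90 against 9 µM, 35 of 35 splits, the real one included, called as many, all 0. With a real count of 0 every split calls as many, so this count could not come out otherwise and decides nothing. Of the 10 splits for each change with time, too few for a share under 0.05, 1, the real one, called as many from 4 to 48 h (real 1318, highest other 0), and 10 did from 4 to 12 h and from 4 to 24 h (real 0, highest other 0). The last 10 were likewise fixed by the real count of 0.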

How the results depend on the processing

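Leaving out the water array at 4 h was chosen only after that array was seen; the other alternatives were planned. No named change reversed past its threshold under the alternatives computed for named genes, which leave out the test of all probes. Of 84 named changes past the threshold, 81 still passed with quantile normalisation repeated, 82 with a trended and robust variance, 59 with ribosomal centring and 74 without the water array at 4 h. Without low-signal genes 70 of 70 did. Of 63, 25 passed without the 90 µM arrays and 23 without the 9 µM arrays. Of 21 for the averages, 19 passed with an additive model, 10 without a time block, and 21, 4, 14 and 15 without the arrays of 4, 12, 24 and 48 h. Counts that moved by over 1.5 times follow, and the cause was not tested unless given. For 900 µM at 4 h, 25 genes became 13 without low-signal genes, 0 with all probes, 0 with ribosomal centring, 1 without the 90 µM arrays, 2 without the 9 µM arrays and 12 without the water array at 4 h. For 12 h, 128 became 35 with all probes, 4 without either low dose and 525 without the water array. For 24 h, 7 became 0 with all probes and without either low dose, 1 with ribosomal centring and 61 without the water array. For 48 h, 0 became 1 without the water array. For the average of 900 µM, 201 became 342 with quantile normalisation, 303 with ribosomal centring, 71 without a time block, 340 without the water array, and 464, 7, 69 and 89 without the arrays of 4, 12, 24 and 48 h. From 4 to 48 h, 1318 became 741 with all probes, 194 without the 90 µM and 153 without the 9 µM arrays, and from 4 to 24 h 0 became 1 with all probes. Leaving out a dose leaves fewer residual arrays, and all probes means more tests. Of lists, with an estimated correlation 0 shifted in every comparison except from 4 to 48 h, where 1 did. The estimated correlation without the water array at 4 h gave 3 lists for 900 µM at 12 h, 1 at 24 h, 4 for its average, 5 from 4 to 48 h, 3 from 4 to 24 h and 0 in the other comparisons. Without the water array 8 instead of 16 lists shifted for 9 µM and 9 instead of 18 from 0 to 4 h. The median of all genes moved under ribosomal centring by -0.32, -0.16, -0.07 and -0.09 for 900 µM at 4, 12, 24 and 48 h, -0.12 for 9 and for 90 µM, -0.14, -0.16 and -0.13 from 4 to 48, 24 and 12 h, and 0.23 from 0 to 4 h. Arrays have no depth, and their number limits precision.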

Other observations

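The single arrays of 90 µM were also set against water and against 9 µM at each time, as values without a test. The median of the 26 p53 targets was 0.51, 0.43, 0.24 and 0.12 above water at 4, 12, 24 and 48 h, and 0.34, 0.17, 0.37 and 0.02 above 9 µM. The 0.51 is against the water array that stood apart, against which 9 µM was at 0.35 for the same list and 90 µM at 0.51 for histones too. The median of the 22 integrated stress response genes was 0.42, -0.28, -0.37 and 0.10 against water and -0.01, -0.11, -0.61 and -0.04 against 9 µM. At 24 h 1 of 22 genes was higher in each, and the 9 µM array was itself 0.24 above water, with 20 of 22 genes higher. At 24 h 131 genes differed by 2-fold or more between 90 and 9 µM, against 3, 4 and 18 at 4, 12 and 48 h.

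In the change with culture time from 4 to 48 h further lists shifted. Nucleolar ribosome biogenesis had 8 of 19 genes lower, and 13 without the water array at 4 h, and a median of -0.34 (camera adjusted p = 1.7e-09, adjusted p = 0.2 with an estimated correlation). B cell identity had 5 of 16 higher and a median of 0.38 (camera adjusted p = 4.6e-06, adjusted p = 0.25 with an estimated correlation). Hypoxia and glycolysis had 8 of 25 higher and a median of 0.29 (camera adjusted p = 0.00039, adjusted p = 0.29 with an estimated correlation), with 0 lower, and 5 lower without the water array at 4 h.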
